A study of Homo sapiens with 16 samples.

How the data were processed

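MicroRNAs were profiled on single-colour Toray 3D-Gene arrays in 16 tumours grown as xenografts from Caco-2 cells, a human colorectal adenocarcinoma line. The titles assign 8 tumours to a control group and 8 to treatment with 90 ug of galectin-9 (Gal-9), and each carries a tissue number from 1 to 8 within its group. Per the labels' protocols, total RNA was labelled with Cy5. The same protocols name serum as the source of the RNA and give doses for cells in culture, while the sample type is a xenograft tumour; the arrays are described here as tumours. The schedule of treatment and the mice behind the tumours are not given in the sources used here, so p-values measure the spread between these tumours only.

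The deposited scanner files hold, per the file headers, the mean and median intensity of each of 3200 spots and a local background intensity on a linear scale. Of the spots, 2019 were probes for human miRNAs (15 of them naming several miRNAs), 925 were blank and 256 were other control or empty spots. No spot average was needed, since each miRNA had 1 spot. The deposited value table holds linear intensity with 2019 rows, all matched by their identifiers. Its columns ranked the probes as the spot means did (lowest Spearman correlation across probes 1.00, against 0.944 for the spot medians), and their medians lay between 229.9 and 230.0. The columns shared 1 distribution, and no subtraction of background was visible in them; the authors' further steps are not given in the sources used here.

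Spot means were corrected with normexp against the local background over all spots (limma 3.58.1 in R 4.3.3, offset 50), taken as log2 and quantile normalised over the miRNA probes. A probe counted as detected on an array when its spot mean exceeded the mean plus 2 SD of the blank spots, after trimming 5% at each end. The 878 miRNAs detected on at least 8 of the 16 arrays were tested. Blank spots averaged 191.5 to 231.2 intensity units per array, and the 99th percentile of the miRNA spots was 3520 to 10526. The number of arrays limits the precision of group means. The probe of miR-4454 was saturated on all 16 arrays and has only a bound. The offset compresses differences of dim probes, and quantile normalisation assumes a common distribution, so a shift shared by most miRNAs would not be seen.

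The groups were compared with limma's lmFit and eBayes, with Benjamini-Hochberg adjustment over the tested miRNAs and a threshold of 0.05 on the adjusted p. All tests were two-sided. Lists of miRNAs were compared with camera, with a preset correlation of 0.01 between members and again with an estimated correlation. Beside it, fry was run; its p tests whether a list's members move on balance in 1 direction, its mixed p whether they change in either direction, and neither compares a list with other miRNAs. List means per array, detection and single values were compared with exact permutation tests over all assignments of the 16 arrays. Of 19 lists, 18 had at least 3 tested members; the list of hypoxia-induced miRNAs had 1 and was not tested. Members were matched by name only, so the probe named miR-133a fell outside the list of muscle markers, which names its arm.

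Named miRNAs followed a rule. It took the 10 called miRNAs with the largest differences each way, or the 10 of smallest p where fewer were called, the called members of each list or else the 2 of highest mean intensity, and the 5 of highest mean intensity over all arrays. Tests, lists, this rule and most alternatives were chosen before the data were examined. Removal of a smooth trend across each array, the median of the spot, the omission of the 2 arrays numbered 7, the omission of single arrays for lists, the omission of single pairs and the estimated correlation under other settings were added after seeing the data. The trend was a robust quadratic surface (MASS 7.3.60.0.1) fitted per array to probes with a mean log2 intensity above 9.

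The labels do not say that tissue numbers pair tumours, and the deposited files of 15 of the 16 arrays carry another number than the tissue number of the title. The tumours of 7 of the 8 pairs share the number of their files as well, while those of pair 1 do not, so the pairing of pair 1 is in doubt. Groups and numbers were taken from the titles. Deviations from the group means correlated over the tested miRNAs between the 2 tumours of each number at 0.16 to 0.86 (median 0.33), against a median of -0.08 for tumours of different number. Deviations cancel out over each group, so positive values within pairs push the other combinations negative, and -0.08 is no independent baseline. Each pair also lay at positions 1 and 2 or 3 and 4, so the comparison does not separate pairing from position. Of the 16 arrays, 7 correlated best with the array of their own number. Pair 7, whose arrays share low values at the right edge, had the highest correlation (0.86), and pair 1 had 0.19. All 8 pairs exceeded 0.1, so a fit with the number as a block of 8 pairs is given where it changes a call. The files give the position of each array on its slide but not the slide. Control arrays were at positions 1 and 3 and Gal-9 arrays at positions 2 and 4, so position was fitted as a random block (consensus correlation -0.05); within positions there is no comparison of groups.

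The fit was tested on simulated data made from the arrays' own residuals, with the arrays shuffled and 200 of 878 miRNAs changed, in 20 runs. The changes were of 0.5, 1, 2 and 3 log2. The fit called 65.1% of miRNAs changed by 0.5 log2 and 95.4% of those changed by 1, with 4.75% false calls. Many large changes ease the adjusted threshold, so these shares do not apply where few miRNAs change, which was not simulated. The list of the miR-17 cluster and its paralogs (13 members), shifted by 1 log2, was called in 20 of 20 runs with either correlation. Smaller lists and smaller shifts were not simulated. With no shift, at least 1 list was called in 18 of 20 runs with the preset correlation and in 0 with the estimated correlation. No miRNA coordinates are given, since no genome build is named in the sources used here. Alternatives covered background correction, normalisation, the deposited value table, filters, variance priors, array weights, blocks, the trend across the array and the omission of arrays.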

Results

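The study examined galectin-9, a lectin that binds beta-galactosides on cell surface glycoproteins, in colon cancer cells and in xenograft tumours. MicroRNAs of 8 control tumours and 8 tumours treated with 90 ug of Gal-9 were measured, with 1 array per tumour and 2019 human miRNA probes per array. Between 608 and 1271 miRNAs were detected per array, 405 on all 16 arrays and 161 on none. Values are normalised intensities on the log2 scale, given as mean ± SD with n = 8 tumours per group, and differences are Gal-9 minus control with the standard error (SE) from limma.

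The tumours of the groups did not differ in how many miRNAs stood above the blank spots. Control arrays detected 937 ± 261 miRNAs and Gal-9 arrays 934 ± 152 (SD, n = 8 each). The difference of -3.38 miRNAs was within the spread between arrays (exact permutation test, two-sided, p = 0.979).

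The comparison of Gal-9 treated with control tumours asked which miRNAs differ after treatment. Among the 10 miRNAs of smallest p, miR-1246 was brighter in treated tumours and the skeletal muscle miRNAs miR-133b, miR-1 and miR-206 were dimmer, but none passed the test. miR-1246, an entry whose sequence matches part of the U2 small nuclear RNA, was at 11.77 ± 0.68 in Gal-9 tumours and 10.68 ± 0.95 in controls, a difference of 1.09 (SE 0.38; 2.13-fold), and was higher in the treated tumour of 8 of 8 pairs with the same number. miR-133b was at 7.22 ± 0.41 against 8.16 ± 0.88, a difference of -0.94 (SE 0.31), and lower in 7 of 8 pairs. Differences beyond 2-fold were seen for 4 of the 878 tested miRNAs, 1 higher (miR-1246) and 3 lower (miR-205-5p, miR-203a and miR-200a-3p), of which miR-205-5p was singled out after its values were seen. This count depended on the background correction, since the offset shrinks differences of dim probes: with the blank mean subtracted and no offset, 58 differed by more than 2-fold, 13 higher and 45 lower.

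With limma, 0 of 878 miRNAs were called (smallest adjusted p = 0.931). At an unadjusted p under 0.05 there were 42 miRNAs, 16 higher and 26 lower, where 43.9 would be reached by chance. With the 8 pairs as a block, 0 were called and 97 had an unadjusted p under 0.05; miR-1246 then had the smallest adjusted p, 0.0649 (SE 0.18). The numbers of the deposited files do not join the tumours of pair 1; with pairs 2 to 8 as a block, 2 miRNAs were called in limma and 155 had an unadjusted p under 0.05. These were miR-5088 (0.94, SE 0.14, adjusted p = 0.0370) and miR-1246 (1.13, SE 0.19, adjusted p = 0.0479), each higher in 7 of 7 pairs; over all 8 pairs miR-5088 differed by 0.59 (SE 0.30, adjusted p = 0.475; 0.0370 to 1 over the alternatives), and it was singled out after its values were seen. With another pair left out in place of pair 1, 0 or 1 were called, miR-1246 without pair 5 (adjusted p = 0.0370). Each position held arrays of 1 group only, so no fit, paired or not, separates position from treatment. With array position as a random block, 0 were called and 51 had an unadjusted p under 0.05. Without control replicate 2 these were 0 and 27, and without control replicate 7 they were 0 and 65. The 95% interval of the difference excluded a 2-fold change either way for 843 of the 878 miRNAs with the offset of 50, and for 379 with the blank mean subtracted.

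**Figure D1:**
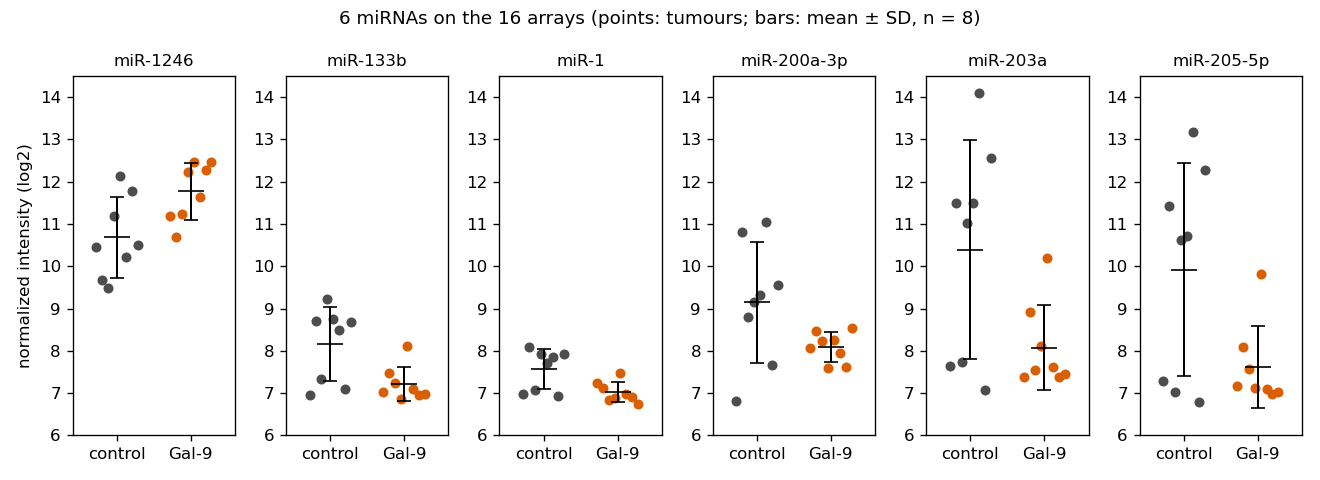
Normalised intensity (log2, vertical axis) of miR-1246, miR-133b, miR-1, miR-200a-3p, miR-203a and miR-205-5p in control and Gal-9 tumours; points are single tumours, bars the mean ± SD of 8. miR-205-5p averaged 9.92 ± 2.52 in controls and 7.61 ± 0.97 in Gal-9 tumours, with 5 control tumours and 1 Gal-9 tumour well above the others.

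The 10 miRNAs of smallest p, all with adjusted p = 0.931 in limma, also included others. Of these, miR-3609 (0.27, SE 0.08), miR-10a-3p, the minor arm of miR-10a (0.32, SE 0.11), miR-4749-3p (0.21, SE 0.07) and miR-320c (0.24, SE 0.09) were brighter in Gal-9 tumours. When the arrays were scaled to a common median these differences were 0.07 (SE 0.19), 0.16 (SE 0.15), 0.02 (SE 0.21) and 0.10 (SE 0.13), in that order. The others were dimmer: miR-1 (-0.54, SE 0.18), miR-206 (-0.53, SE 0.18), miR-708-5p (-0.53, SE 0.19) and miR-3943 (-0.31, SE 0.10). With the blank mean subtracted and no offset the differences of dim miRNAs were larger, and none passed the test (smallest adjusted p = 0.590 in limma). They were -2.44 (SE 0.79) for miR-1, -3.63 (SE 0.88) for miR-206, -2.20 (SE 0.97) for miR-708-5p, -1.69 (SE 0.58) for miR-3943, -2.17 (SE 0.72) for miR-133b, 0.88 (SE 0.23) for miR-3609 and 0.36 (SE 0.19) for miR-4749-3p; miR-206 was then at the lowest value allowed on 3 arrays and miR-708-5p on 2. Several lay near the blank spots. miR-206 was detected in 7 of 8 control and 2 of 8 Gal-9 tumours, miR-1 in 7 and 3, miR-133b in 8 and 4, and miR-708-5p in 7 and 3.

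The brightest probes did not separate the groups. Quantile normalisation gives the brightest ranks fixed values, so close means of these probes were in part set by it. miR-5100 was at 15.08 in control tumours 3 and 8, with spot means of 21510 and 52974. miR-4454 was saturated on every array, so no difference can be given. miR-5100 averaged 15.01 ± 0.13 in Gal-9 and 14.93 ± 0.44 in control tumours, miR-1260b 14.71 ± 0.26 and 14.77 ± 0.21, miR-3960 14.03 ± 0.69 and 13.93 ± 0.66, and miR-23b-3p 13.81 ± 0.69 and 13.63 ± 1.02. The order of the groups turned for miR-5100 when the arrays were scaled to a common median (-0.01) or normalised by cyclic loess (-0.16). miR-23b-3p, low in control tumour 7 (11.22), ranged from -0.16 to 0.41 over the alternatives and changed direction in 2 of 40.

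Of the lists, skeletal muscle markers and the miR-200 family had the largest mean differences. All 3 tested skeletal muscle markers were dimmer in Gal-9 tumours (mean difference -0.67). In the miR-200 family, which represses the transcription factors ZEB1 and ZEB2 and marks epithelial cells, 4 of 5 members were dimmer (mean difference -0.68). miR-200a-3p was at 8.09 ± 0.36 against 9.14 ± 1.43 and miR-200b-3p at 7.81 ± 0.28 against 8.65 ± 0.91, while miR-429 differed by 0.15 (SE 0.09). Lists of leukocyte and of fibroblast and smooth muscle markers had mean differences of -0.23 (-0.38 when the arrays were scaled to a common median) and -0.25, and the imprinted 14q32 cluster, a large group of miRNAs expressed from the maternal chromosome, had one of 0.13.

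In camera with the preset correlation, 5 of 18 lists were called. The adjusted p was 3.04e-05 for skeletal muscle markers, 0.0105 for the miR-200 family, 0.0105 for leukocyte markers, 0.0181 for fibroblast and smooth muscle markers and 0.0254 for the 14q32 cluster. None of these calls held with an estimated correlation: adjusted p = 0.173 with an estimated correlation for skeletal muscle, 0.664 for the miR-200 family, leukocyte and fibroblast lists, and 0.709 for the 14q32 cluster. The correlation estimated between members was 0.82 for skeletal muscle and 0.66 for the miR-200 family. Single tumours also decided calls with the preset correlation. The fibroblast list was not called without control replicate 2 (adjusted p = 0.0721), control replicate 3 (0.180) or Gal-9 replicate 7 (0.163), and the leukocyte list not without control replicate 6 (0.205) or 8 (0.0555). With the trend across the array removed and the pairs as a block, camera did not call the fibroblast list either (adjusted p = 0.0659). The 14q32 cluster was not called without control replicate 2, 6 or 7 or Gal-9 replicate 1, 3 or 6 (adjusted p 0.0515 to 0.301), nor with pairs 2 to 8 as a block (0.0864). With fry, 0 lists were called (smallest adjusted p = 0.171, skeletal muscle), and the exact permutation test of list means called 0 (smallest adjusted p = 0.0965). Shuffled arrays without any difference gave at least 1 list call in 18 of 20 runs with the preset correlation, so the 5 calls are listed with their values and not as changes.

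**Figure D2:**
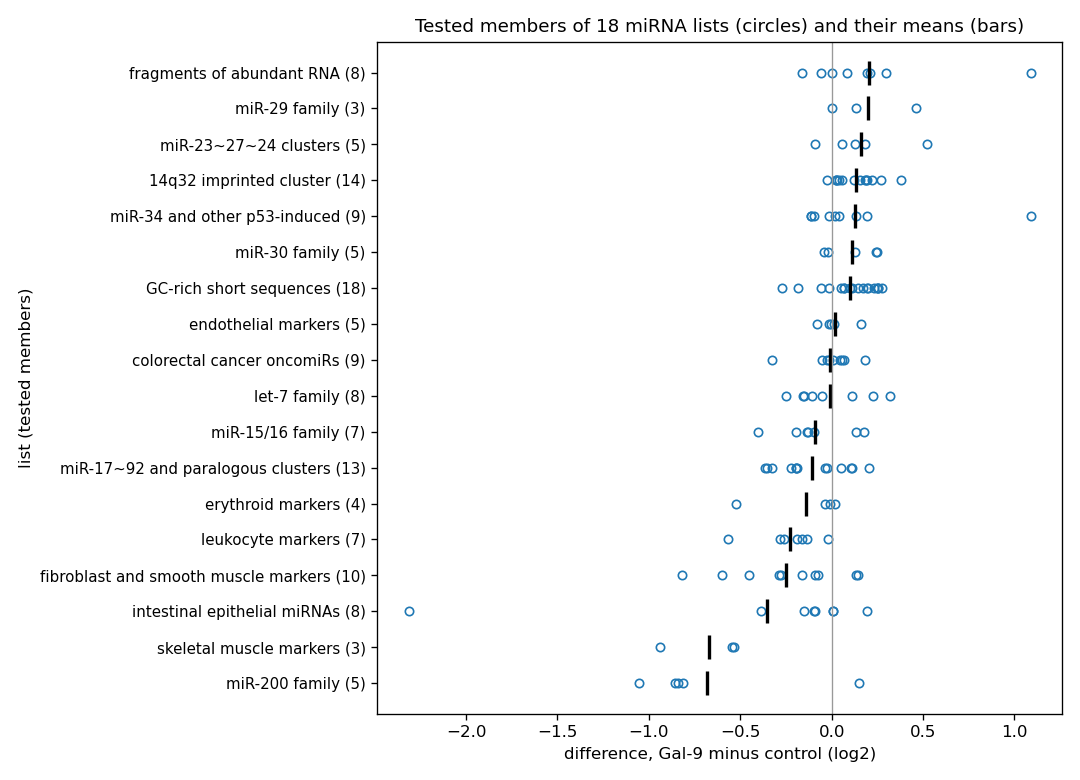
Differences between Gal-9 and control tumours (log2, horizontal axis) of the tested members of 18 miRNA lists; circles are miRNAs, bars the mean of each list, and the number of tested members stands after its name. Skeletal muscle markers and the miR-200 family have the lowest means, -0.67 and -0.68.

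Skeletal muscle markers were the only list with members passing when p-values were adjusted over the list alone. Of its 3 tested members, 3 passed adjusted over the list alone (smallest p so adjusted 0.00805 in limma) and 0 over all miRNAs tested. In the miR-200 family, 3 members had an unadjusted p under 0.05 and 0 passed adjusted over the list alone. Each of the other 16 lists also had 0 members called over all miRNAs and 0 adjusted over the list alone. miR-203a and miR-205-5p, which mark skin and other stratified epithelium, were also dimmer in Gal-9 tumours without passing the test. miR-203a was at 8.08 ± 1.0 against 10.39 ± 2.59, and in 6 tumours, 5 control and 1 Gal-9, the mean of the pair was at least 10.00, against at most 8.51 in the other 10. These 6 tumours were also the 6 with the highest mean of the skeletal muscle markers.

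Among markers of other host cells, leukocyte miRNAs were dimmer for 7 of 7 tested members. The myeloid miR-223-3p was at 8.44 ± 0.39 against 9.00 ± 0.68 and miR-342-3p differed by -0.19 (SE 0.15). In the fibroblast and smooth muscle list, 8 of 10 members were dimmer, with values of -0.07 (SE 0.21) for miR-125b-5p and 0.14 (SE 0.30) for miR-100-5p; miR-125b-5p turned to 0.05 when the arrays were scaled to a common median. The list of fibroblast markers was not called under that scaling (adjusted p = 0.461). Endothelial markers had 2 members higher and 3 lower, with a mean difference of 0.02, turning to -0.05 when scaled to a common median (where camera still placed the list above the other miRNAs), and a median just under 0 (camera adjusted p = 0.862); miR-126-3p differed by -0.08 (SE 0.28) and miR-221-3p by -0.01 (SE 0.13). Of 4 erythroid markers 1 was higher and 3 were lower (mean -0.14, or -0.23 under that scaling; adjusted p = 0.623); miR-451a was at 10.39 ± 1.32 against 10.92 ± 1.08, and miR-486-5p differed by -0.01 (SE 0.10).

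No member of the lists known from colon cancer passed the test. In the miR-17 cluster and its paralogs, which MYC induces, 9 of 13 members were lower (mean -0.11, camera adjusted p = 0.0998), with miR-17-5p at 10.82 ± 0.34 against 11.19 ± 0.41 and miR-106a-5p at 10.99 ± 0.49 against 11.18 ± 0.52. miR-17-5p was lower in 7 of 8 pairs (-0.36, SE 0.10 with the pairs as a block; limma adjusted p = 0.367). With the pairs as a block this list was called (adjusted p = 0.0214; adjusted p = 0.533 with an estimated correlation). It was also called without control replicate 1, 5 or 7 or Gal-9 replicate 3, 6 or 8 (adjusted p 0.00757 to 0.0489; adjusted p 0.492 to 0.672 with an estimated correlation), with pairs 2 to 8 as a block (0.00121; adjusted p = 0.292 with an estimated correlation), and with the trend across the array removed, without the block (0.0333; adjusted p = 0.512 with an estimated correlation) or with it (0.0297; adjusted p = 0.494 with an estimated correlation). Of 9 tested oncomiRs of colorectal cancer, 5 were higher and 4 lower (mean -0.01, or -0.05 when scaled to a common median, where camera placed the list above the other miRNAs; median 0.01, adjusted p = 0.949); miR-21-5p differed by 0.04 (SE 0.45) and miR-31-5p by 0.01 (SE 0.18), which turned to -0.06 with cyclic loess. The intestinal epithelial list had 5 of 8 members lower (mean -0.35, median -0.09, adjusted p = 0.144), among them miR-203a at -2.31 (SE 0.88), and was called without Gal-9 replicate 8 (adjusted p = 0.0462; adjusted p = 0.630 with an estimated correlation) and with pairs 2 to 8 as a block (0.0445; adjusted p = 0.292 with an estimated correlation).

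The let-7 family, which represses RAS and MYC messages, had 3 members higher and 5 lower (mean -0.01, turning to 0.02 when scaled to a common median; adjusted p = 0.949). let-7a-5p differed by 0.11 (SE 0.47) and let-7d-5p by -0.16 (SE 0.33). Over the alternatives let-7a-5p ranged from -0.29 to 0.35 and changed direction in 4 of 40, and let-7d-5p ranged from -0.39 to 0.05 and changed in 1. Both were low in control tumour 7 (10.71 and 11.26). In the miR-34 and p53-induced list, 5 of 9 were higher (mean 0.13, or 0.01 when scaled to a common median; median 0.02, adjusted p = 0.761), and miR-107 differed by -0.11 (SE 0.19). The miR-15/16 family had 5 of 7 lower (mean -0.09, adjusted p = 0.346; miR-16-5p -0.20, SE 0.21; miR-15b-5p 0.13, SE 0.40). Under scaling to a common median its mean was still -0.09, but camera placed it above the other miRNAs. miR-15b-5p, low in control tumour 7 (8.94), ranged from -0.16 to 0.34 over the alternatives and changed direction in 2 of 40.

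The remaining lists had positive means and were not called. They were the miR-30 family (3 of 5 higher, mean 0.11, adjusted p = 0.623), the miR-29 family (2 of 3 higher, mean 0.20, adjusted p = 0.346), the miR-232724 clusters (4 of 5 higher, mean 0.16, adjusted p = 0.623), GC-rich short sequences (14 of 18 higher, mean 0.10, adjusted p = 0.548) and entries overlapping fragments of abundant RNA (5 of 8 higher, mean 0.21, adjusted p = 0.254). With the preset correlation all 5 were called when the arrays were scaled to a common median (adjusted p 0.000171 to 0.00908), where the median difference of all tested miRNAs was -0.13 in place of 0.02. None of these calls held with an estimated correlation (adjusted p 0.0587 to 0.434 with an estimated correlation under that scaling, and 0.664 to 0.920 without it). GC-rich sequences were also called with pairs 2 to 8 as a block (adjusted p = 0.00106; adjusted p = 0.447 with an estimated correlation). In these lists miR-30a-5p differed by 0.25 (SE 0.22), miR-30d-5p by 0.24 (SE 0.33), miR-29a-3p by 0.13 (SE 0.14), miR-29b-3p by 0.46 (SE 0.27), miR-23a-3p by 0.52 (SE 0.37) and miR-6089 by -0.27 (SE 0.15). In the 14q32 cluster 13 of 14 members were higher, with miR-376c-3p at 0.27 (SE 0.19) and miR-379-5p at 0.04 (SE 0.29); the mean of the cluster was 0.05 under scaling to a common median. Both arrays numbered 7 had low values for let-7a-5p, let-7d-5p, miR-15b-5p, miR-30d-5p and miR-23b-3p, whose probes lie at the right edge of the array; without these arrays limma called 0 miRNAs (50 at an unadjusted p under 0.05) and camera 5 lists. Over the alternatives, the mean of the miR-30 family ranged from 0.01 to 0.20, and camera's direction changed in 2 of 26. The mean of the miR-232724 clusters ranged from 0.005 to 0.27, with 1 change of direction. miR-30d-5p ranged from -0.01 to 0.41.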

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

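The tests of explanations in this part were chosen after the results were seen, except the counts of other splits of the samples with all 16 tumours; the split count with pairs 2 to 8 rests on an omission chosen after the data were seen. In 122 groups of 8 values, 17 held a tumour far from the others, where chance gives about 1 in 20. That rate does not hold for the brightest probes, since the normalisation gives many arrays the same value.

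Of these 17, 11 were control or Gal-9 tumours numbered 7 with low normalised values. In control tumour 7 they were miR-1260b (14.32), miR-23b-3p (11.22), let-7a-5p (10.71), let-7d-5p (11.26), miR-15b-5p (8.94), miR-30d-5p (9.23), the mean of the miR-232724 clusters (11.18) and the mean of the fibroblast and smooth muscle markers (9.09). In Gal-9 tumour 7 they were miR-23b-3p (12.24), let-7a-5p (11.91) and the mean of the miR-232724 clusters (11.63). For miR-1260b only the normalised rank was low. Its spot mean in control tumour 7 (36084) was exceeded among the controls by control tumour 8 alone (39074). Other tumours far from their group were control tumour 1 for miR-5100 (13.85), control tumour 3 for miR-6089 (12.28), and Gal-9 tumour 2 for miR-342-3p (9.35) and the mean of the leukocyte markers (8.36). For miR-5100 the normalisation gave all other control tumours the same value, 15.08. Gal-9 tumour 8 was high for the mean of the miR-200 family (8.24) and Gal-9 tumour 5 for the mean of the skeletal muscle markers (7.58).

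In the tumours numbered 7, the low values of the families named next followed the place of the probe on the array. This was not examined for miR-1260b or for the fibroblast and smooth muscle markers. Of the let-7, miR-15/16, miR-232724 and miR-30 families, the 9 bright members at the right edge were lower on these 2 arrays than on the other 14 by a median of -1.85, and the 13 printed elsewhere by a median of -0.47 (SE 0.23), which left lower families in these tumours undecided; the difference between the means of these sets, a test added after that one, was -1.61 (SE 0.20), which argues against lower families as the whole cause. Spike Control 1, which is not tumour RNA, was also low at the right edge relative to its other spots, by -0.43 and -0.18 on these arrays (mean -0.31) against -0.05 to 0.42 on the other 14, so signal lost over part of the array is a candidate explanation. The drop of the spike was smaller than that of the right-edge family members. Bright probes of any kind differed by a median of -1.70 at the right edge (25 probes, -2.57 to 0.77) and 0.20 elsewhere (123 probes, -2.29 to 1.75). A smaller decrease of these families in the tumours themselves stays open, since members printed elsewhere were also lower on balance. No biological explanation in the design concerns the number 7.

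The muscle, miR-200 and skin miRNAs were lower in Gal-9 tumours on balance, and highest in largely the same tumours. Of the 6 arrays with the highest mean of miR-205-5p and miR-203a, 6 were also the highest 6 for skeletal muscle markers. For the miR-200 family 5 of them were. This may point to host skin and muscle taken with some tumours (5 control and 1 Gal-9). The arrays were those of control tumours 2, 4, 6 and 8, all control arrays at slide position 3, and of both tumours numbered 5. Among controls the pattern thus largely followed position, which was not separated from host tissue, while no Gal-9 array at position 4 was among the 6. The files do not separate mouse from human miRNAs, and the miR-200 family is also made by tumour cells. A smooth loss of signal across the array is argued against by a mean difference of the 5 skin and muscle miRNAs of -1.33 before and -1.29 after its removal. This covers only a trend of the fitted form, which was fitted to bright probes, while the muscle miRNAs were dim. With the trend removed, pair 7 still correlated at 0.86, so a loss confined to the edge may remain and was not tested. A larger share of host cells of every kind in the controls stays open: the difference of muscle from endothelial (-0.69, SE 0.22, exact permutation p = 0.00808), leukocyte (-0.44, p = 0.0260) and erythroid markers (-0.53, p = 0.0253) changed between groups, but that from fibroblast and smooth muscle markers was within the spread (-0.42, SE 0.26, p = 0.122), and leukocyte and fibroblast lists were lower on balance as well (-0.23 and -0.25). The SEs of these differences between lists come from the spread between arrays, without limma. An effect of Gal-9 on the tissue around or in the tumour stays open and was not tested apart from these explanations.

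miR-1246 was higher in the treated tumour of 8 of 8 pairs. With a smooth trend across each array removed, the difference was 1.13 (SE 0.34, limma adjusted p = 1) in place of 1.09. This argues against a trend of the fitted form as its cause, while a loss confined to the edge was not tested. With the pairs fitted too, the SE was 0.16 (limma adjusted p = 0.0146), and over the alternatives the adjusted p ranged from 0.0146 to 1. More fragments of abundant RNA of every kind is argued against by the other 6 measurable entries of that list. Their median difference was 0.14 (SE 0.09, from the spread between these entries and not between tumours). They ranged from -0.16 to 0.30, and the normalisation holds miR-5100 and miR-1260b among them near fixed values. Chance could not be excluded: with the pairs fitted, 5 of 100 splits that part all 8 pairs, the real one included in both counts, gave a smallest adjusted p as low as the real 0.0649, the lowest of the others being 0.0143. In every pair the control array was at position 1 or 3 of the slide and the Gal-9 array at position 2 or 4. Position and treatment therefore cannot be told apart, also with the pairs fitted. An effect of Gal-9 on miR-1246 is a hypothesis that these tumours leave open.

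Other splits of the 16 tumours gave results as large as the real one. The counts of splits here include the real one. Of 100 splits, 37 had at least the real 42 miRNAs at an unadjusted p under 0.05 (highest other 316) and 25 had at least the real 5 lists called with the preset correlation (highest other 11), so chance cannot be excluded for either count. The real split called 0 miRNAs, a count that any of the 100 splits reaches (highest other 115), so the splits say nothing about it. Only 4 of the 100 splits called any miRNA, and the median count at an unadjusted p under 0.05 was 28.5. The few splits that call far more than the real one therefore do not show a structure of the samples apart from the treatment. A split by position on the slide, positions 3 and 4 against 1 and 2, called 0 miRNAs (smallest limma adjusted p = 0.322). It had 79 miRNAs at an unadjusted p under 0.05 and 6 lists called with the preset correlation. Each pair lies within 1 side of that split, so the block of pairs removes it. The block does not remove position within a pair, where the control and Gal-9 arrays always differ in it. With the pairs fitted, 8 of 100 splits that part all 8 pairs had at least the real 97 miRNAs (highest other 157), so chance cannot be excluded for this count. With pairs 2 to 8 fitted, 1 of 64 splits that part these pairs had at least the real 2 called, the real one (highest other 1); this does not exclude chance, since pair 1 was left out after the data were seen and the omission of any other single pair gave 0 or 1.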

How the results depend on the processing

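Settings that remove the trend across the array, use the spot median or leave out the arrays numbered 7 or single pairs, and for lists single arrays and the estimated correlation under other settings, were chosen after seeing the data. In 37 of 40 alternatives limma called 0 miRNAs; over all 40 there were 22 to 155 at an unadjusted p under 0.05 (27 to 65 when single arrays were left out). With the trend removed and the replicate block 1 miRNA was called, 1 higher, miR-1246; with pairs 2 to 8 and the replicate block 2 were called, 2 higher (155 at an unadjusted p under 0.05), and with pair 5 left out and the replicate block 1, 1 higher; the cause was not tested. Leaving out each of the other pairs in turn gave 63 to 93 at an unadjusted p under 0.05. The replicate block alone gave 0 called and 97 at an unadjusted p under 0.05, array weights 89, no filter 100 of 2019, and detection on all arrays 22 of 405, where fewer were tested. Subtraction of the blank mean without an offset gave 58 miRNAs beyond 2-fold in place of 4. Without the trend removed, the block of all 8 pairs changed no other call than that of the list of the miR-17 cluster and its paralogs. Of 18 lists camera called 9 when arrays were scaled to a common median, which moved the median difference of all tested miRNAs from 0.02 to -0.13, and 0 with an estimated correlation, which allows for members that vary together, with or without that scaling; with pairs 2 to 8 as a block it called 7. Leaving out single arrays gave 3 to 7 lists, 3 without control replicate 2 and 3 without control replicate 6; skeletal muscle and miR-200 lists were called in all 16 of these, the 14q32 cluster in 10. The difference in detected miRNAs was -29.2 with a threshold at 3 SD (exact permutation p = 0.739) and 18.6 without the arrays numbered 7 (p = 0.874). Of 49 named miRNAs, 31 showed no change of direction, counting the saturated miR-4454, whose difference of 0 has none to keep. Of 1951 values, 86 changed sign, none of them called. Scaling to a common median moved 20 of the 49 by over 1.5 times or across 0. Probes close to the blank spots, such as that of miR-206, limit what can be seen of dim miRNAs.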

Other observations

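The tests in this part were chosen after the data were seen. miR-146b-5p was at 8.25 ± 0.68 in Gal-9 and 9.12 ± 0.88 in control tumours (n = 8), lower in 7 of 8 pairs, with a limma adjusted p of 0.931 and 0.367 with the pairs as a block. The probe shared by miR-199a-3p and miR-199b-3p was at 10.42 ± 0.37 against 11.24 ± 0.87. miR-133a, which the list of muscle markers missed by its name, differed by -0.59 (SE 0.22), or -1.54 (SE 0.59) with the blank mean subtracted, on the side of miR-133b. The mean of miR-205-5p and miR-203a, chosen after their values were seen, differed by -2.31 between groups (exact permutation p = 0.0357).

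Control arrays at position 3 of a slide had miR-205-5p higher by 3.92 than those at position 1 (4 arrays each, limma adjusted p = 0.358), and Gal-9 arrays at position 4 differed from those at position 2 by -0.55 (adjusted p = 0.991). The median local background was 163.2 ± 1.26 intensity units at position 1, 156.8 ± 1.5 at position 2, 151.5 ± 3.11 at position 3 and 140.5 ± 4.20 at position 4 (SD, 4 arrays each). Of 22 probes named S-Probe with a 4-digit number, whose targets the files do not name, 4 had an exact permutation p under 0.05 and 0 passed adjustment (smallest adjusted p = 0.154).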
